A study of Mus musculus with 8 samples.

How the data were processed

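Poly(A)-selected RNA of mouse embryonic stem cells of the E14 line, grown with serum and leukaemia inhibitory factor, was sequenced on an Illumina instrument from libraries made with the TruSeq RNA kit, per the labels' protocols. The labels describe 8 samples in 4 groups of 2 biological replicates: wild type, a knockout of the long noncoding RNA lncSmad7, and the same knockout transfected with lncSmad7 or with Smad7. The descriptions of the Smad7-transfected samples name 24 h. The authors deposited a table of raw read counts per gene symbol with 55292 features. STAR and featureCounts 1.6.3 are named in the submitters' processing notes, together with the mouse builds mm10 and GRCm38, with no role or order. The annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here.

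The deposited counts of 6 columns were used, each of which names a group and replicate that the labels also give. A further 2 columns matched no sample's labels and were not used in any step, so the group transfected with lncSmad7 was not analysed here. Of 6 comparisons planned, 3 were run, and the fit planned over 8 libraries became a fit over 6. The total counts per library lay between 13392941 and 20209760. A test of the counts of replicates against sampling noise, over genes with at least 10 counts, gave a chi-square per degree of freedom of 1.57 in wild type, 1.72 in the knockout and 1.89 in the libraries labelled Smad7-transfected knockout, so no library was taken for a second deposit of another. These values do not tell separate cultures from repeat libraries of 1 culture.

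Genes were filtered with filterByExpr, which left 17342, and scaled with TMM factors. The main test was edgeR's quasi-likelihood test with robust estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3) over all 6 libraries in a fit with 3 groups and 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Normalised CPM values use the TMM factors, and means are given with the SD over 2 libraries. The common biological coefficient of variation was 2.47%. On simulated data with known changes for the comparison of the labelled Smad7-transfected knockout with the knockout, over 15625 genes, the test recovered 54% of 50 genes changed 1.25-fold, 84% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. Of 203 calls in that simulation 165 were these genes, 20 belonged to a set of 30 genes shifted 1.2-fold, and 18 were false. That is 8.87%, above the share that the threshold of 0.05 sets. Few genes were changed in the simulation, while 12945 of 17342 passed in the data. It therefore does not test the scaling or the error rate under so broad a difference.

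Genes were named by a rule fixed before the data were examined. It took the 8 genes with the greatest rise and the 8 with the greatest fall past the threshold in each main comparison, and 4 each way in the third. Their libraries had to be separate between groups, their mean had to reach 5 CPM, and clone names were left out. The rule added up to 4 members of each list with the smallest adjusted p, and always Smad7, lncSmad7, Ep300, Crebbp, Pou5f1, Nanog, Sox2, Klf4, Bmp2, Bmp4, Id1, Id2, Id3, Lefty1, Lefty2 and Nodal. Some genes that the rule names are not reported here.

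There were 25 gene lists, also fixed beforehand. They covered core pluripotency, naive pluripotency, formative and primed pluripotency, mesoderm and primitive streak, endoderm, neuroectoderm, trophectoderm, 2-cell-like cells, fibroblasts and feeder cells, activin, nodal and TGF-beta targets, BMP targets and ligands, receptors and Smads of the TGF-beta superfamily, and histone acetylation machinery. The others were immediate early and ERK targets, Wnt targets, interferon response, p53 targets, integrated stress and unfolded protein response, sterol biosynthesis, glycolysis and hypoxia, cell cycle, imprinted genes, germline genes sensitive to DNA methylation, Hox genes, and mitochondrial transcripts. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 24 lists within a comparison. Camera compares the listed genes with all others.

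Positions and biotypes came from the GENCODE mouse annotation release 21 (GRCm38), matched by symbol, and 53186 symbols had a single position. Chromosome medians were tested by permuting genes over chromosomes, two-sided, with Benjamini-Hochberg adjustment over chromosomes. Alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in 4 libraries, a fit of only the 4 libraries compared, a replicate block, a minimum log2 fold of 1, each replicate left out in turn, camera with estimated correlations, and fry. Alternatives added after seeing the data were library size scaling, offsets per library for GC content and transcript length (mgcv 1.9.3, with values for 97.9% of genes tested), glmTreat against a fold of 1.5, and autosomal genes only. Drawing and permutations used Python 3.11.15.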

Results

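The data are read counts per gene from 6 libraries of mouse E14 embryonic stem cells, a line from a male embryo. The groups were wild type, a knockout of the long noncoding RNA lncSmad7, and the same knockout labelled as transfected with Smad7, an inhibitor of TGF-beta superfamily signalling, each with 2 libraries. Total counts were 19260386 and 20209760 in wild type, 20159897 and 19455030 in the knockout, and 13392941 and 15972163 in the libraries labelled Smad7-transfected knockout. Mitochondrial transcripts took 1.58% and 1.53% of counts in wild type, 1.40% and 1.37% in the knockout, and 2.48% and 2.33% in the libraries labelled Smad7-transfected knockout. Genes for ribosomal proteins took 4.49% and 4.68%, 4.93% and 5.20%, and 3.39% and 3.34% in the same order. The first principal component held 71.2% of the variance and separated the 3 groups, and replicates lay together on it. The series describes the replicates as biological, with no further word on separate cultures, so p-values measure the spread between these libraries, which may be technical.

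The target genes were examined first. The lncSmad7 feature stood at 13.2 ± 1.1 CPM in wild type (SD, n = 2), 6.33 ± 1.1 in the knockout and 10.99 ± 0.30 in the libraries labelled Smad7-transfected knockout. Its raw counts were 237 and 221, 140 and 105, and 167 and 207. It fell in the knockout (log2 fold −1.05, SE 0.12, adjusted p = 3.0e-14) and was higher in the libraries labelled Smad7-transfected than in the knockout (0.79, SE 0.13, adjusted p = 9.3e-09). Smad7 lies at chromosome 18, 75367529 to 75395935, on the plus strand of GRCm38. It stood at 97.6 ± 0.048 CPM, 72.5 ± 4.2 CPM and 96.6 ± 3.9 CPM, fell in the knockout (−0.43, SE 0.048, adjusted p = 5.9e-15) and was 1.33-fold higher in the libraries labelled Smad7-transfected (log2 fold 0.41, SE 0.048, adjusted p = 3.2e-14). A rise of lncSmad7 is not what a label of Smad7 transfection names, and Smad7 only reached its wild-type level. For this reason these libraries are called labelled Smad7-transfected throughout, and every direction drawn from them rests on that label. However, the log2 fold of lncSmad7 lay near the median of lincRNAs between these groups (0.80, with 274 of 484 higher). Its rise alone therefore does not show a wrong label. The position of the lncSmad7 feature relative to the deleted interval is not given in the sources used here, so the reads left in the knockout check neither the deletion nor its extent.

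**Figure D1:**
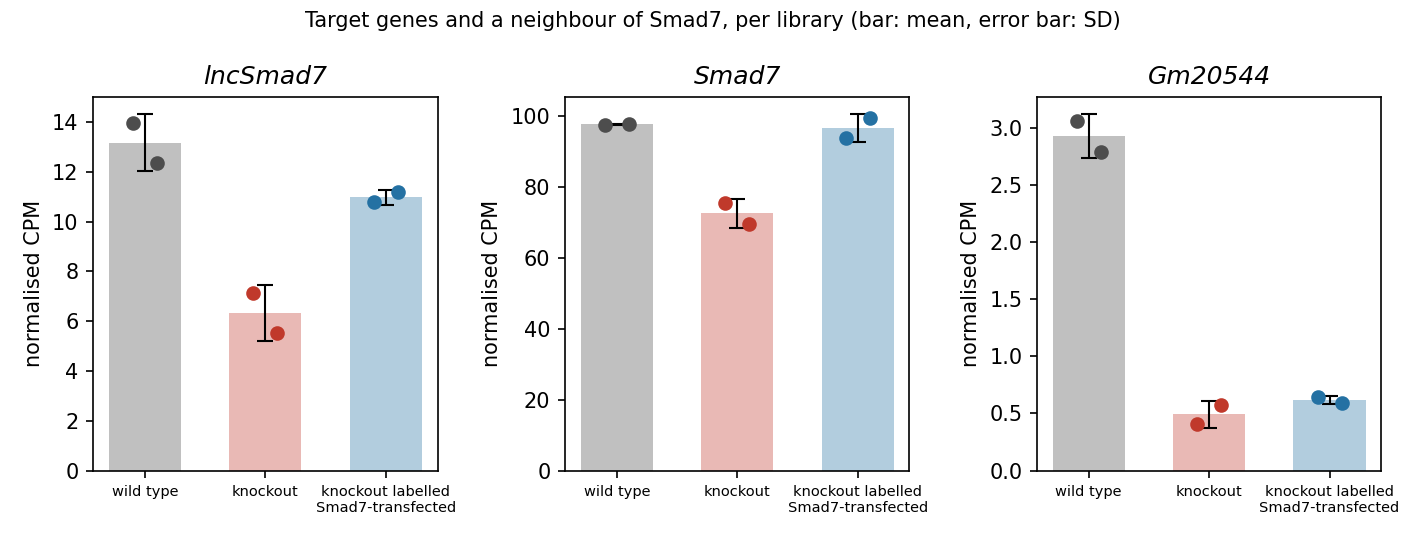
Normalised CPM of lncSmad7, Smad7 and Gm20544 in each library of wild type, knockout and labelled Smad7-transfected knockout; points are libraries, bars are means and error bars the SD over 2 libraries. lncSmad7 and Smad7 are lowest in the knockout, at 6.33 and 72.5 CPM, while Gm20544 is low in both knockout groups.

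The comparison of knockout with wild type asks, by its labels, what the loss of lncSmad7 changes in untreated stem cells. Expression from the X and Y chromosomes also differed between these groups, as given below. For the genes and lists that follow, loss of lncSmad7 therefore cannot be told apart from other differences between the knockout and wild-type cells. Stc1, which encodes the secreted hormone stanniocalcin, had 0 counts in wild type and 113 in the knockout, at least 34.0-fold higher against a floor of 3 counts over the group, which covers counting error only. Ndufa4l2, a mitochondrial protein induced in low oxygen, rose from 0.404 ± 0.096 to 27.3 ± 0.64 CPM (log2 fold 6.06, SE 0.18). Tex13b on the X chromosome (4.69), the transcriptional repressor Bhlhe41 (4.41), the cadherin Fat2 (4.35), the nuclear receptor Hnf4a (4.31), Mst1 (4.27) and Matn1 (4.16) also rose, with SEs from 0.14 to 0.28. Cubn, an endocytic receptor of the visceral endoderm, fell by 5.85 on the log2 scale (SE 0.17). The imprinted gene Peg10 (−5.57), the endocytic adaptor Dab2 (−5.26), the growth factor receptor Pdgfra (−3.69) and Eya1 (−3.61) also fell. The Y-linked genes Ddx3y, Uty and Eif2s3y changed by −5.65, −4.93 and −4.32. By edgeR's quasi-likelihood test 11747 of 17342 genes passed the threshold, 5977 higher and 5770 lower, of which 3976 had a log2 fold of at least 1 in size, 2460 higher and 1516 lower. The balance of calls at any fold turned with the method: the share of higher calls, 50.9% in the main test, was 61.7% with library size scaling, 46.8% with RLE scaling, 47.1% with GC and length offsets and 46.7% by DESeq2. The median log2 fold of all genes was 0.02 in the main test, 0.17 with library size scaling, −0.03 with RLE scaling and −0.02 with GC and length offsets.

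Genes of glycolysis and the hypoxia response rose together. Of 27 measured, 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 fold of 1.30. The glycolytic enzyme Pgk1 rose from 211 ± 0.12 to 1045 ± 1.4 CPM, the glucose transporters Slc2a1 and Slc2a3 rose by log2 folds of 1.94 and 1.55, and Pfkp by 1.67. Camera gave an adjusted p of 3.6e-23, and adjusted p = 0.11 with an estimated correlation. Naive pluripotency genes went the same way, with 13 of 18 higher and 5 lower (13 and 5 adjusted over the list alone), and camera gave an adjusted p of 4.7e-07 (adjusted p = 0.11 with an estimated correlation). Klf2, Klf4 and Klf5, transcription factors that sustain naive pluripotency, rose by 1.79, 1.601 and 1.19, and Tcl1 rose by 1.81.

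Cell cycle genes fell, 19 of 30 lower and 5 higher (19 and 5 adjusted over the list alone), with Cenpf at −2.76, Cenpe at −2.23 and the proliferation marker Mki67 at −2.21 (camera adjusted p = 5.5e-05; adjusted p = 0.19 with an estimated correlation). Endoderm genes fell, 14 of 20 lower and 4 higher (14 and 4 adjusted over the list alone), with the basement membrane collagen Col4a1 at −2.25 and Cubn and Dab2 above, while the lipoprotein Apoe (1.66) and Hnf4a rose (camera adjusted p = 0.0024; adjusted p = 0.20 with an estimated correlation). The de novo DNA methyltransferase genes Dnmt3a (−2.38), Dnmt3l (−0.70) and Dnmt3b (−0.66) fell with 10 of 16 formative and primed genes, against 3 higher (10 and 4 adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.25 with an estimated correlation). The p53 targets had 11 of 21 higher and 4 lower, among them Perp (2.00), a membrane protein of cell death and adhesion, and the integrated stress and unfolded protein list had 15 of 24 higher and 6 lower, among them Vldlr (3.68) and Chac1 (2.94). Both lists had the same counts adjusted over the list alone, an adjusted p of 0.025 by camera, and adjusted p = 0.25 with an estimated correlation. The replicate block ended the calls of the formative and p53 lists (adjusted p = 0.11 and 0.074), and the GC and length offsets that of the integrated stress list (0.13). Without wild-type replicate 1 the formative list was not called (adjusted p = 0.080).

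The other lists were not called in this comparison, and their counts adjusted over the list alone differed by at most 2 genes. Core pluripotency had 5 of 12 genes higher and 6 lower (camera adjusted p = 0.22), with Zfp281 at −1.43 and Tdgf1 at 0.87. Imprinted genes had 6 of 23 higher and 15 lower (0.063), and were called without wild-type replicate 2 (0.044) or knockout replicate 1 (0.049). Of the others, mesoderm and primitive streak genes had 3 of 12 higher and 6 lower (0.56). Neuroectoderm had 6 of 14 higher and 5 lower (0.60), trophectoderm 6 of 10 higher and 2 lower (0.50), and fibroblasts and feeder cells 5 of 7 higher and 0 lower (0.17). Of the immediate early and ERK targets 11 of 20 were higher and 6 lower (0.11), with Egr1 at 2.05 and Myc at −2.39. Wnt targets had 6 of 13 higher and 4 lower (0.72), and interferon genes 5 of 16 higher and 4 lower (0.64); in both the mean was negative while the median and the test pointed up. Sterol biosynthesis had 4 of 22 higher and 12 lower (0.11), with Idi1 at −1.98, and was called with GC and length offsets (median −0.38, adjusted p = 0.012). Germline genes sensitive to DNA methylation had 6 of 15 higher and 5 lower (0.61), Hox genes 5 of 8 higher and 0 lower (0.53), and mitochondrial transcripts 0 of 7 higher and 4 lower (0.16). With GC and length offsets the mitochondrial list was called upward (adjusted p = 6.2e-04) and without knockout replicate 1 downward (0.049), so it has no direction here. Of the 18 genes of 2-cell-like cells, Ddit4l (1.02) and Calcoco2 (−0.22) were the 2 measured, too few for a set test, and Calcoco2 did not pass by DESeq2 (adjusted p = 0.13), with library size scaling or without wild-type or knockout replicate 1.

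The signalling genes fixed beforehand split. The BMP-responsive inhibitors Id1, Id2 and Id3 changed by −0.96 (SE 0.038), −0.68 (SE 0.052) and −0.45 (SE 0.075) in the knockout, while Bmp4 (−0.01) and Bmp2 (−0.14) did not pass the test. The nodal pathway genes Lefty2 (0.91) and Nodal (0.48) rose, and Lefty1 fell (−0.18). Of the activin, nodal and TGF-beta targets 7 of 21 were higher and 11 lower (camera adjusted p = 0.60), with the repressor Bhlhe40 at 3.27, Skil at −1.34 and Ccn1 at −3.48. BMP targets and ligands had 4 of 17 higher and 7 lower (0.59), and receptors and Smads 7 of 20 higher and 6 lower (0.56), with Smad3 at 1.66 and Bmpr2 at −1.65. The acetyltransferases Ep300, which encodes p300, and Crebbp fell (−0.40 and −0.44), in a histone acetylation list with 11 of 25 higher and 10 lower (0.73), which turned downward with GC and length offsets without passing. Nanog (0.47) and Sox2 (0.49) rose, and so did Pou5f1 (0.17), which did not pass with GC and length offsets (0.044, adjusted p = 0.12). Id3, Nodal, Lefty1, Ep300, Crebbp, Pou5f1, Nanog and Sox2 did not pass glmTreat, and Lefty1 did not pass with library size scaling (−0.036, adjusted p = 0.48). Bmp4 passed in opposite directions with GC and length offsets (−0.18) and library size scaling (0.13).

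Around Smad7, 15 genes within 1000000 bp on chromosome 18 were tested and 12 passed the threshold. Among all genes tested 67.7% passed in this comparison, so the count alone does not show a local effect. Gm20544, a noncoding transcript on the minus strand at 75365332 to 75367088 and 441 bp from the start of Smad7, fell by 2.56 (SE 0.32, adjusted p = 8.3e-13), from 52 and 50 counts to 8 and 11. The transcription factor gene Zbtb7c rose by 1.88, while the lipase Lipg (−1.602), Myo5b (−0.79), Acaa2 (−0.70) and Smad2 (−0.33) fell. DESeq2 called 7 of these genes, without Myo5b (adjusted p = 0.087), and glmTreat 4. Without a stated strand setting, reads of overlapping transcripts on opposite strands cannot be separated.

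By chromosome, genes of the X rose in the knockout: 428 of 631 were higher and 67 lower, and their median lay 0.87 above that of the other chromosomes (1.82-fold; permutation test, adjusted p = 7e-05). The median of the 6 Y-linked genes measured differed from the other chromosomes by −3.79 on the log2 scale, with 4 lower and 0 higher (permutation test, adjusted p = 7e-05). Autosomal shifts were smaller, with −0.23 on chromosome 11 (adjusted p = 7e-05), −0.17 on 13 (1e-04), −0.14 on 15 (0.001), −0.10 on 3 (0.012) and 0.09 on 6 (0.015). The p of 1e-05 before adjustment for X, Y and 11 is the smallest these permutations can give. With GC and length offsets chromosome 3 moved to 0.01 and 13 to −0.04, and neither passed. Chromosome 6 did not pass without either knockout library (adjusted p = 0.068 and 0.074). Among autosomal genes alone, 11040 passed, 5444 higher and 5596 lower.

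**Figure D2:**
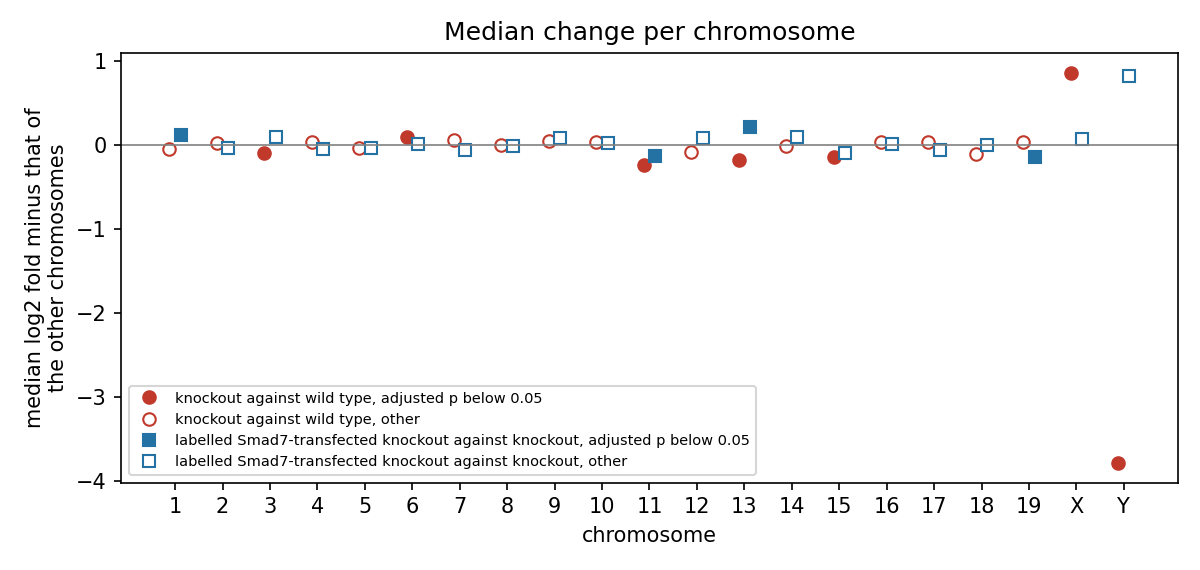
Median log2 fold of the genes of each chromosome minus that of the other chromosomes, for knockout against wild type (circles) and labelled Smad7-transfected knockout against knockout (squares); filled symbols have a permutation adjusted p below 0.05. The X lies at 0.87 and the Y at −3.79 in the knockout against wild type.

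The comparison of the labelled Smad7-transfected knockout with the knockout asks, by its labels, what added Smad7 changes in the knockout, although the lncSmad7 feature also rose between these groups. Nlrc5, an activator of MHC class I genes, was higher by 3.998 on the log2 scale (SE 0.18), from 1.01 ± 0.35 to 16.3 ± 1.3 CPM. Sec14l5 (3.70), the germ cell gene Tex15 (3.66), Igip (3.61), the noncoding Snhg14 (3.41), Ano3 (3.37), the keratin Krt19 (3.37) and the ubiquitin ligase Rnf128 (3.34) followed, with SEs from 0.083 to 0.16. The growth factor Fgf17 was lowest, at −2.69 (SE 0.12), from 26.2 ± 1.7 to 4.05 ± 0.25 CPM. Pirt (−2.42), Rnd1 (−2.32), Zfp771 (−2.19), Calcoco2 (−2.15), Tmem238 (−2.14) and the noncoding Lncenc1 (−2.10) were also lower. By edgeR's quasi-likelihood test 12945 genes passed, 6558 higher and 6387 lower, of which 4467 had a log2 fold of at least 1 in size, 3279 higher and 1188 lower. Of such folds, library size scaling gave 4287 higher and 587 lower, and GC and length offsets 3509 and 645. At any fold the share of higher calls, 50.7% in the main test, was 65.7% with library size scaling and 57.2% with GC and length offsets, but 45.3% by DESeq2, 49.6% with no filter on low counts and 48.7% to 49.6% with each replicate left out. The median log2 fold was 0.04 in the main test, 0.29 with library size scaling and 0.14 with GC and length offsets. The mitochondrial share of counts was higher and the ribosomal protein share lower in the labelled Smad7-transfected libraries. They had fewer counts in total, yet 26358 and 27359 genes with a count, against 24849 and 24777 in the knockout. Among lincRNAs, antisense transcripts and unconfirmed transcripts, more were higher than lower, as given below. These differences between libraries were not tested as a source of the changes.

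Targets of p53 rose: 18 of 21 were higher and 2 lower (18 and 2 adjusted over the list alone), with a median of 1.08. The p53 inhibitor Mdm2 rose from 153 ± 7.8 to 428 ± 4.7 CPM, the cyclin Ccng1 by 1.45, the DNA polymerase Polk by 1.88 and the kinase Plk2 by 1.49 on the log2 scale. Camera gave an adjusted p of 4.7e-14, and adjusted p = 0.076 with an estimated correlation. Core pluripotency genes fell, 10 of 12 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 1.9e-06; adjusted p = 0.12 with an estimated correlation). Trim28 changed by −1.43, Utf1 by −1.29, Nanog by −0.93 and Pou5f1 by −0.89. Naive pluripotency genes fell, 15 of 18 lower and 1 higher (16 and 1 adjusted over the list alone), with Klf2 at −1.09 and Klf4 at −0.59 (camera adjusted p = 3.0e-06; adjusted p = 0.12 with an estimated correlation). Sox2 stood at −0.26, which turned to 0.13 with GC and length offsets and did not pass with library size scaling (−0.013). Markers of fibroblasts and feeder cells had 6 of 7 higher and 0 lower, the same adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.11).

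Cell cycle genes had 23 of 30 lower and 5 higher (23 and 5 adjusted over the list alone; camera adjusted p = 8.3e-04; adjusted p = 0.39 with an estimated correlation). The cyclin Ccne1 changed by −1.48, yet Cenpe (2.05), Mki67 (1.90) and Cenpf (1.86), which encode kinetochore proteins and a proliferation marker, rose. Glycolysis and hypoxia genes had 18 of 27 higher and 9 lower (18 and 9 adjusted over the list alone), with the hypoxia-induced genes Egln3 (2.08), Ndrg1 (1.80) and Vegfa (1.71) higher (camera adjusted p = 0.0012; adjusted p = 0.43 with an estimated correlation). The members that fell included the glycolytic enzymes Ldha (−0.71), Eno1 (−0.63) and Tpi1 (−0.61), chosen after their values were seen. Histone acetylation genes had 18 of 25 lower and 6 higher, with Hdac1 at −0.93 and Hat1 at −0.71 (camera adjusted p = 0.027; adjusted p = 0.44 with an estimated correlation). Endoderm genes had 14 of 20 higher and 1 lower, with Col4a1 at 1.32 (camera adjusted p = 0.044; adjusted p = 0.43 with an estimated correlation), and imprinted genes 10 of 23 higher and 7 lower, with Kcnq1ot1 at 2.32 (camera adjusted p = 0.044; adjusted p = 0.39 with an estimated correlation). These 3 lists had the same counts adjusted over the list alone, and the imprinted call was lost with GC and length offsets (adjusted p = 0.46). Without knockout replicate 2 neither the endoderm nor the imprinted list was called (adjusted p = 0.052 for both), nor was the imprinted list without labelled Smad7-transfected replicate 1 or 2 (0.11 and 0.072).

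Targets of activin, nodal and TGF-beta, which include Smad7 itself, had 15 of 21 higher and 4 lower. These counts were the same adjusted over the list alone. The median was 0.55, with Skil at 0.94 and Nodal at 0.67 (camera adjusted p = 0.068). The GC and length offsets gave that list an adjusted p of 0.0087, and it was also called without labelled Smad7-transfected replicate 2 (0.032). Receptors and Smads had 13 of 20 higher and 6 lower (camera adjusted p = 0.072), with Bmpr2 at 1.94. Lefty2 (0.17) was higher and Bmp4 lower at −0.59. Bmp2 (1.63) was higher on 25 counts against 9, and did not pass by DESeq2 (adjusted p = 0.15), without knockout replicate 1 (0.069) or without labelled Smad7-transfected replicate 1 (0.059). In the main test Id1 (0.05), Id2 (0.07), Id3 (−0.08) and Lefty1 (−0.05) did not pass. Id1 and Id2 passed with GC and length offsets (0.50 and 0.36), library size scaling (0.29 and 0.32) and the 1 CPM filter (0.15 and 0.18), and Id3 and Lefty1 reached 0.33 and 0.28 with GC and length offsets. The integrated stress list had 9 of 24 higher and 13 lower (camera adjusted p = 0.67), with a mean above and a median below 0, and turned upward with GC and length offsets without passing. Crebbp was higher by 0.40, and Ep300 stood at −0.13, which turned to 0.12 with library size scaling and did not pass with the 1 CPM filter (−0.027). Klf4, Sox2, Bmp4, Lefty2, Crebbp and Ep300 did not pass glmTreat. All 7 mitochondrial transcripts measured were higher (camera adjusted p = 0.068, 1.8e-05 with the replicate block, and 0.0017 to 0.022 without knockout replicate 1 or either labelled Smad7-transfected replicate), but mt-Nd2 turned to −0.16 and mt-Cytb to −0.03 with GC and length offsets. The X (0.07) and Y (0.83) medians did not pass the permutation test (adjusted p = 0.23 and 0.13), but 4 of the 6 Y-linked genes were higher and 0 lower. Of these Uty (1.80, adjusted p = 2.6e-08), Ddx3y (1.48, 2.6e-06) and Eif2s3y (0.86, 3.9e-06) remained far below wild type. Chromosomes 13 (0.22, adjusted p = 2.1e-04), 1 (0.13, 0.0036), 11 (−0.13, 5.2e-04) and 19 (−0.14, 0.022) passed that permutation test.

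**Figure D3:**
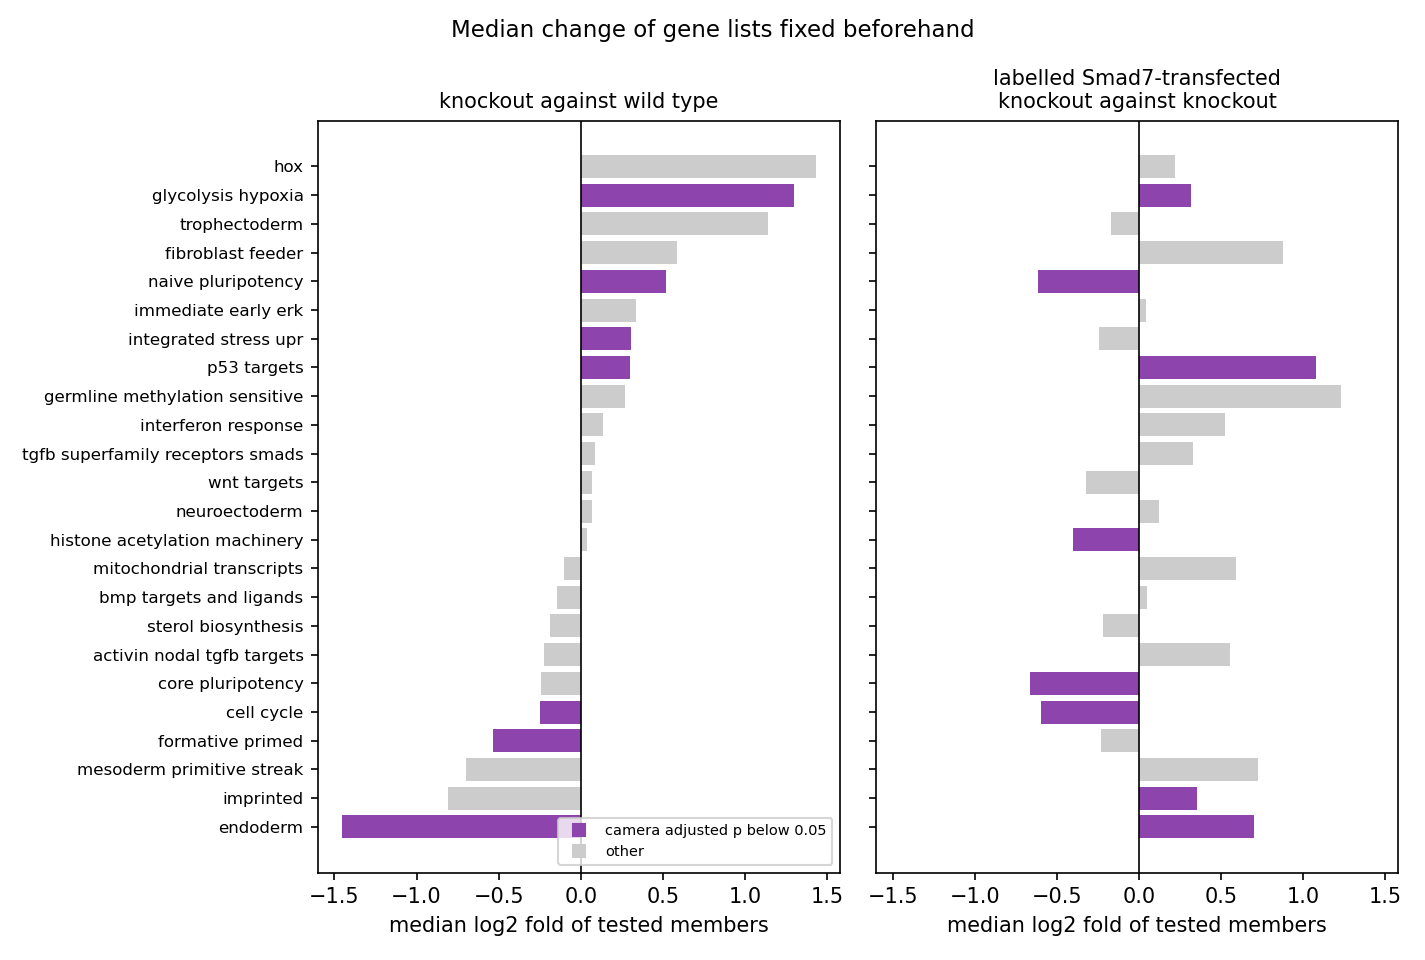
Median log2 fold of the measured members of each of 24 gene lists, for knockout against wild type on the left and labelled Smad7-transfected knockout against knockout on the right; purple bars have a camera adjusted p below 0.05 at a preset correlation of 0.01. Glycolysis and hypoxia genes lie at 1.30 on the left, and p53 targets at 1.08 on the right.

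The comparison of the labelled Smad7-transfected knockout with wild type asks how far these cells stay from wild type. Stc1 was at least 196-fold higher against the same floor, and Ndufa4l2 (7.54), Vldlr (6.36) and Mst1 (6.33) were the other genes with the greatest rise. Peg10 (−6.47), Cubn (−4.90), Dab2 (−4.26) and Ddx3y (−4.17) had the greatest fall. Smad7 did not differ from wild type (−0.01, SE 0.047, adjusted p = 0.79), but turned to 0.38 with library size scaling and to −0.29 with GC and length offsets, both past the threshold. The lncSmad7 feature was lower by edgeR (−0.26, adjusted p = 0.027), and was not called by DESeq2 (−0.31, adjusted p = 0.19) or with library size scaling (0.13). In all 14198 genes passed, 7469 higher and 6729 lower, of which 7457 had a log2 fold of at least 1 in size, 4749 higher and 2708 lower. Of such folds, library size scaling gave 6174 higher and 1316 lower. At any fold the share of higher calls, 52.6% in the main test, was 68.3% with that scaling and 49.1% by DESeq2, and that scaling moved the median log2 fold from 0.09 to 0.48.

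In that comparison 5 lists were called, and the counts of each were the same adjusted over the list alone. With GC and length offsets 10 were called, which added the formative and primed, histone acetylation, sterol biosynthesis, germline and mitochondrial lists. Glycolysis and hypoxia genes had 23 of 27 higher and 3 lower (camera adjusted p = 1.5e-11; adjusted p = 0.33 with an estimated correlation), and p53 targets 18 of 21 higher and 3 lower (camera adjusted p = 1.1e-08; adjusted p = 0.17 with an estimated correlation). Cell cycle genes had 27 of 30 lower and 2 higher (camera adjusted p = 7.1e-09), core pluripotency genes 10 of 12 lower and 2 higher (6.2e-04), and fibroblast and feeder genes 7 of 7 higher (0.032). For these 3 lists adjusted p = 0.33 with an estimated correlation.

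Whether the knockout's changes turn back in the labelled Smad7-transfected libraries was asked over the 11747 genes called in knockout against wild type. Of these, 3720 (31.7%) were called the opposite way and 5447 (46.4%) the same way. Independent lists would give 2260 genes higher in both steps, where 2528 were found, 2125 lower in both, where 2919 were found, 2201 higher and then lower, where 1898 were found, and 2182 lower and then higher, where 1822 were found. Genes called with a log2 fold of at least 1 in size split otherwise: of those that fell, 913 then rose, against 573 by independence, and 171 fell again, against 558, while of those that rose 1260 rose again, against 930, and 418 then fell, against 906. Of these genes 33.5% were called the opposite way and 36.0% the same way. Over genes, which are not independent replicates, Pearson's r was −0.00, Spearman's rho 0.10 and the covariance −0.0012. Both comparisons share the knockout libraries, and 20 simulations of unchanged groups gave a mean r of −0.469, a covariance of −0.0196 and at most 1 opposite call. The simulated groups held no true changes, so their r is noise alone and no benchmark for the r found. Sharing alone gave almost no opposite calls there, but genes truly changed in 1 of the steps were not simulated. The 2 knockout libraries were not split between the comparisons, so part of any opposite change may come from sharing them. With either knockout library left out, r went to −0.16 and −0.12. Both comparisons then still shared the 1 knockout library left, so these values are not free of sharing.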

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

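Library size scaling, the GC and length offsets, glmTreat and the autosomal restriction were chosen after seeing the data. The planned comparisons and alternatives with the lncSmad7-transfected group were not run. Of the values of named genes under the alternatives, 5253 of 5513 kept direction and side of the threshold, 156 lost and 37 gained the call, 38 called in either setting reversed, and 29 turned direction without a call. Of those of gene lists 481 of 576 kept both, 29 lost and 56 gained the call, and 9 turned direction without a call. The mitochondrial list in knockout against wild type reversed with GC and length offsets (median 0.63). With a replicate left out, the single library left in its group is assumed to vary like the other groups. The replicate numbers did not pair the samples (correlation of deviations across genes at most 0.026), and with the replicate block 11822, 12982 and 14219 genes passed in the knockout against wild type, the labelled Smad7-transfected knockout against the knockout, and against wild type. The cause of each change given here was not tested, except that fewer genes remained with stricter filters or a minimum fold.

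In the same order, glmTreat left 4749, 6004 and 9203 genes and a minimum log2 fold of 1 left 3976, 4467 and 7457. The filter of 1 CPM left 2419 and 4822 genes with such a fold in the last 2 comparisons. Lists called were 0 in each with an estimated correlation, 20, 19 and 21 with fry, and 10 with GC and length offsets in the last. Of the genes around Smad7, glmTreat left 4 and DESeq2 7 in the first comparison, and glmTreat 2 in the second; Smad7 itself (−0.43 and 0.41) did not pass glmTreat.

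Against wild type, Smad7 reversed to 0.38 with library size scaling and passed at −0.29 with GC and length offsets, with or without the block. There lncSmad7 reversed to 0.13 with library size scaling. It did not pass with the 1 CPM filter (−0.15), the offsets (−0.19, and −0.18 with the block), glmTreat (−0.26) or DESeq2 (−0.31), nor without wild-type replicate 1 or either labelled Smad7-transfected replicate, and leaving out each replicate gave −0.37 to −0.19.

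Library size scaling also reversed Bmp4 (0.13) and mt-Co1 (0.042) in the first comparison, Ep300 (0.12), Lefty1 (0.20), Tfap2c (0.032) and Smad2 (0.070) in the second, and Crebbp (0.35), Lefty1 (0.16), mt-Nd1 (0.037) and Dym (0.23) in the last. The offsets, with the block or without it, reversed Rian (0.10), mt-Nd1 (0.63), mt-Co1 (0.59) and mt-Nd4 (0.56) in the first. In the second they reversed Sox2 (0.13), Id3 (0.33), Lefty1 (0.28), Tfap2c (0.028, and 0.025 with the block), Tcf7 (0.046, and 0.045 with the block), mt-Nd2 (−0.16), mt-Cytb (−0.029, and −0.028 with the block) and BC031181 (0.13), and in the last mt-Nd1 (0.29) and Ctif (−0.040, and −0.049 with the block).

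Among chromosome medians in knockout against wild type, the offsets turned 3 to 0.0079, weakened 13 (−0.041) and brought 5 past the threshold (−0.078). Genes of at least 5 CPM gave 0.028 for 6, which did not pass, and 0.088 for 7, which did. Leaving out each replicate gave 0.067 to 0.088 for 6, 0.045 to 0.071 for 7 and −0.094 to −0.070 for 12, with the test passing for 7 without knockout replicate 1 or wild-type replicate 1 and for 12 without wild-type replicate 1. The share of genes called the opposite way stayed between 29.5% and 32.2% with each replicate left out.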

Other observations

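The tests of wild-type cells, of exchanged transfected groups, of activin, nodal and TGF-beta targets and of a missing Y chromosome, and the comparison of biotypes, were chosen only after the result was seen; the test of X segments was set after the X median had been seen but before the values of the segments.

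In the labelled Smad7-transfected knockout against the knockout, 274 of 484 lincRNAs were higher and 42 lower, with a median log2 fold of 0.80 (1.07 with GC and length offsets and 1.04 with library size scaling). Of 490 antisense transcripts 202 were higher and 33 lower (median 0.52). That median was 0.92 with GC and length offsets and 0.77 with library size scaling. Of 449 unconfirmed transcripts of the TEC class 279 were higher and 11 lower (median 1.09). Of 1080 pseudogenes 214 were higher and 494 lower, with a median of −0.65, or −0.15 with GC and length offsets. Of 13901 protein-coding genes 5255 were higher and 5598 lower, with a median of −0.01 that turned to 0.24 with library size scaling. No set test was run on these classes.

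The lncSmad7 feature rose in libraries labelled as transfected with Smad7. Wild-type cells mixed into them would return every gene lost in the knockout towards wild type alike, but 18 genes far below wild type in the knockout (log2 fold of −3 or less, set after the data were seen) returned by a median of 6.41% (quartiles 1.83% and 17.0%), with Ddx3y at 3.71%, Uty at 8.48% and Eif2s3y at 4.26%, against 68.1% for lncSmad7. This argues against such cells as the whole source of the lncSmad7 rise, although 2 of the 18 genes returned past the midpoint. A small share of such cells is not excluded, since Ddx3y, Uty and Eif2s3y also rose. A stricter form of the test needed nearly all genes to stay under the midpoint and left such cells open. It was dropped after its outcome was known. An exchange of the transfected groups stays open and cannot be told apart from a true effect: the Smad7 log2 fold over the knockout lay at percentile 65.4 of all genes, and the other transfected group was not analysed here. The rise of lncSmad7 alone does not point to an exchange, since it lay near the lincRNA median of 0.80 between the same groups. What sequence was transfected is not given in the sources used here, and no biological explanation was tested.

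The labelled Smad7-transfected knockout differed broadly from the knockout. GC content and transcript length as the whole cause are argued against, since 72.3% of the genes past the threshold with a log2 fold of at least 1 in size, 3228 of 4467, stayed so with the offsets. The 2 directions differed: such genes went from 3279 to 3509 higher, but from 1188 to 645 lower. The share that stayed was not counted for the lower genes alone, so GC content and length are not argued against for these. Lower activin, nodal and TGF-beta signalling through Smad7 was not settled. In the main test camera pointed upward but did not call the listed targets (adjusted p = 0.068). The values lean away from lower signalling: the targets had a median of 0.55, from 0.51 to 0.80 over 16 settings. Of these targets 15 of 21 were higher and 4 lower, and Smad7 itself (0.41) is 1 of those higher. Fry called the list upward (adjusted p = 0.0013), and so did camera with GC and length offsets (0.0087). The test also set the median against the SD of 0.83 between members. That SD is a spread of single genes and not the error of their median, so it cannot decide the question. Earlier forms of this test, which asked for a median above 0 together with an upward call by fry or a median above 0 in every setting, argued against lower signalling and were changed after the value was known. The labels name no batch and no mock-transfected libraries were used here, so the effects of transfection and of library preparation were not tested.

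The Y-linked genes Ddx3y, Uty and Eif2s3y stood at 1.97%, 3.26% and 4.99% of wild type in the knockout, and at 5.60%, 11.5% and 9.03% in the labelled Smad7-transfected knockout, each higher than in the knockout. A Y chromosome missing from most cells stays open. These 3 genes changed by −5.65 to −4.32 (SD between genes 0.66) and Gm29650, with 10 and 17 counts in wild type and 1 and 2 in the knockout, by −3.21 (SE 0.67), but Uba1y, also on the Y, stood at 1.89 CPM in wild type and 1.58 in the knockout (−0.26, SE 0.27, adjusted p = 0.39). These 5 genes share under 10% of their 50-base words with genes outside the Y. Uba1y goes against a missing Y, but lies under 2 CPM, which was taken as too low to decide alone. That rule was written after these values were known, and Gm29650 (0.77 CPM in wild type) lies under 2 CPM too. The sharing limit was set after Gm47283, which shares 60.3% and stood at 0.06, had been seen. Earlier forms of the test, dropped after their outcomes were known, went against a missing Y with Gm47283 counted and for it with the 3 genes alone. Reads from X-linked copies are argued against for Ddx3y, Uty and Eif2s3y only. These genes and their copies differed by a median of 1.53 in the labelled Smad7-transfected knockout against the knockout. No X-linked copy was compared for Uba1y. That gene shares 0.64% of its 50-base words with genes outside the Y, which leaves little room for exact matches from such a copy. Reads with mismatches were not tested. An additional X chromosome stays open. The median of X segments above the autosomes ran from 0.36 to 1.06, and 8 of 9 segments reached the bound of 0.5 that the test asked of all. The copies Ddx3x (−1.07), Kdm6a (0.08) and Eif2s3x (0.39) did not move together. Clonal differences between the knockout and wild-type cells, and loss of lncSmad7 itself, were not tested as sources.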
